A study of Gallus gallus with 12 samples.

How the data were processed

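Total RNA from the breast muscle of 12 birds was labelled from 150 ng with the Affymetrix whole-transcript kit and hybridised to whole-transcript arrays, 1 array per bird, per the labels' protocols. The submitters' processing notes name Partek, with no version or role. The background correction, the summarization method and the genome build are not given in the sources used here. The values deposited by the authors are read here as log2 expression per transcript cluster, 1 row per cluster and 1 column per array. The log base is not stated and was inferred from the range of 1.04 to 12.9. Array medians lay close together without being equal, and whether and how the arrays had been scaled is not stated. All 12 columns were used and none was left out.

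Clusters were named from the platform's annotation, with symbols updated through Entrez IDs in a gene table of assembly GRCg7b, which was used only for names and for which chromosome a gene lies on. Of 20804 clusters 12300 had 1 gene symbol, 256 had several and 8248 had none listed, and 11727 clusters were matched through an Entrez ID. Clusters with several symbols were not named. A gene with more than 1 cluster, which was the case for 651 of 11528 genes, was represented by the cluster with the highest mean over all arrays. Exactly repeated rows numbered 895, of which 11 were among the calls.

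Groups came from the phenotype label. The replicate numbers follow the order of deposition and pair no birds. Differences, affected minus normal, were fitted on the values as deposited with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 3.39, residual 10) and adjusted by the Benjamini-Hochberg method over all 20804 clusters, with a threshold of 0.05. A second count required a log2 difference of at least 1. Standard errors are limma's moderated ones. Gene lists with at least 5 measured members, 32 in all, were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry. Members were matched by exact symbol. Counts adjusted over the list alone apply the Benjamini-Hochberg method within the list. Principal components were computed on cluster-centred values, and group scores were compared by an exact two-sided permutation test over all 924 arrangements. Figures were drawn with matplotlib 3.10.9.

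The samples, tests, gene lists, alternatives and naming rule were fixed before the data were examined. The rule took the 15 largest rises and the 12 largest falls among named genes at an adjusted p under 0.05, up to 4 members of each list past that threshold or otherwise the 1 member with the smallest p, and the 3 named genes with the smallest p. Placeholder symbols were left out. Alternatives were quantile normalization, median centring, 2 filters on dim clusters, other variance models, array weights, named clusters only, other set tests, the mean of all clusters of a gene, and leaving out each array. Fits without the 3 arrays with W-chromosome transcripts (HINTW above 6 on the log2 scale), with HINTW as a covariate, on autosomal genes, with repeated rows counted once, without normal bird 2 and affected bird 4 together, and an exact permutation of list means were added after the data were seen. No scan batch was given in the labels. The numbers in the sample titles run from 1 to 10 for normal birds and from 11 to 20 for affected birds. If they follow the order of collection or processing, an effect of that order cannot be told apart from the phenotype.

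The fit was tested on simulated data made from these arrays, with 20804 clusters of which a known part was changed, and with 1 gene list shifted. For 6 against 6 arrays it recovered 34.8%, 82.1% and 97.0% of clusters changed by 0.5, 1 and 2 on the log2 scale, with 1.33% of calls false. Camera called the shifted list, citric acid cycle, and 1 other, oxidative phosphorylation, which shares 3 of its shifted members. For 3 normal against 6 affected arrays it recovered 16.7%, 67.2% and 94.0%, with 3.15% false. Noise was drawn for each cluster on its own, while genes of a list are correlated on the real arrays. The recovered and false shares and the list calls may therefore differ there. Outside the shifted list, only clusters above a fixed mean level were changed.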

Results

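Transcript levels were measured in the Pectoralis major, the large white breast muscle, of 12 Ross broilers, a fast-growing commercial meat chicken. All birds came from 1 flock raised to an average live weight of 3.7 kg. At slaughter 6 fillets had been classed as normal and 6 as affected by white striping with wooden breast, a muscle disorder seen as white lines along the fibres and a hardened fillet. Each bird gave 1 whole-transcript array, so n = 6 per group throughout and the replicates are separate birds. The table held 20804 transcript clusters on every array, each value being a log2 level. Array medians ran from 4.05 to 4.16, and correlations between arrays from 0.941 to 0.987.

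The design asks which transcripts differ between affected and normal breast muscle. Affected muscle had higher levels of CSRP3 (a stress-responsive protein of the muscle Z-disc), of MB (myoglobin, the oxygen-binding protein of red muscle) and of COL12A1 (a collagen that coats fibrils), and lower levels of AMPD1, the AMP deaminase of fast fibres. CSRP3 was 9.87-fold higher and MB was 5.17-fold higher, and for both genes all 6 affected birds lay above every normal bird. In limma's fit over all clusters, 238 clusters passed an adjusted p of 0.05, with 131 higher and 107 lower in affected muscle. Of these, 42 differed by at least 2-fold, 23 higher and 19 lower. Among the called clusters 143 carried 1 gene symbol, 100 higher and 43 lower, 5 carried several and 90 had no gene listed. The first principal component held 29.7% of the variance and separated the groups. Scores were -20.5 ± 10.5 (SD, n = 6) in normal and 20.5 ± 12.7 in affected muscle, with an exact two-sided permutation p of 0.00216, the smallest that the 924 arrangements can give. With the 11691 named autosomal clusters only, chosen after the data were seen, the difference was 24.5 (exact permutation p = 0.00649). There the scores overlapped, the lowest affected bird being at -3.86 and the highest normal bird at -1.91. This setting also drops every cluster without 1 gene symbol, and scores depend on the number of clusters. The change therefore cannot be credited to the sex chromosomes.

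These counts depended on single birds. The call count was 50, 91, 59, 22 and 437 without normal birds 1, 2, 3, 4 and 6, and 588, 25, 25, 37 and 1 without affected birds 1, 2, 3, 4 and 6. In each of these fits all 238 clusters kept the sign of their difference, as is likely for clusters chosen on mostly the same arrays. The 2-fold count ran from 1 to 81 when 1 bird was left out, and of the 42 called genes that are discussed by name here, between 1 and 41 remained past the test. With each array centred on its median, 225 clusters were called higher and 117 lower.

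**Figure D1:**
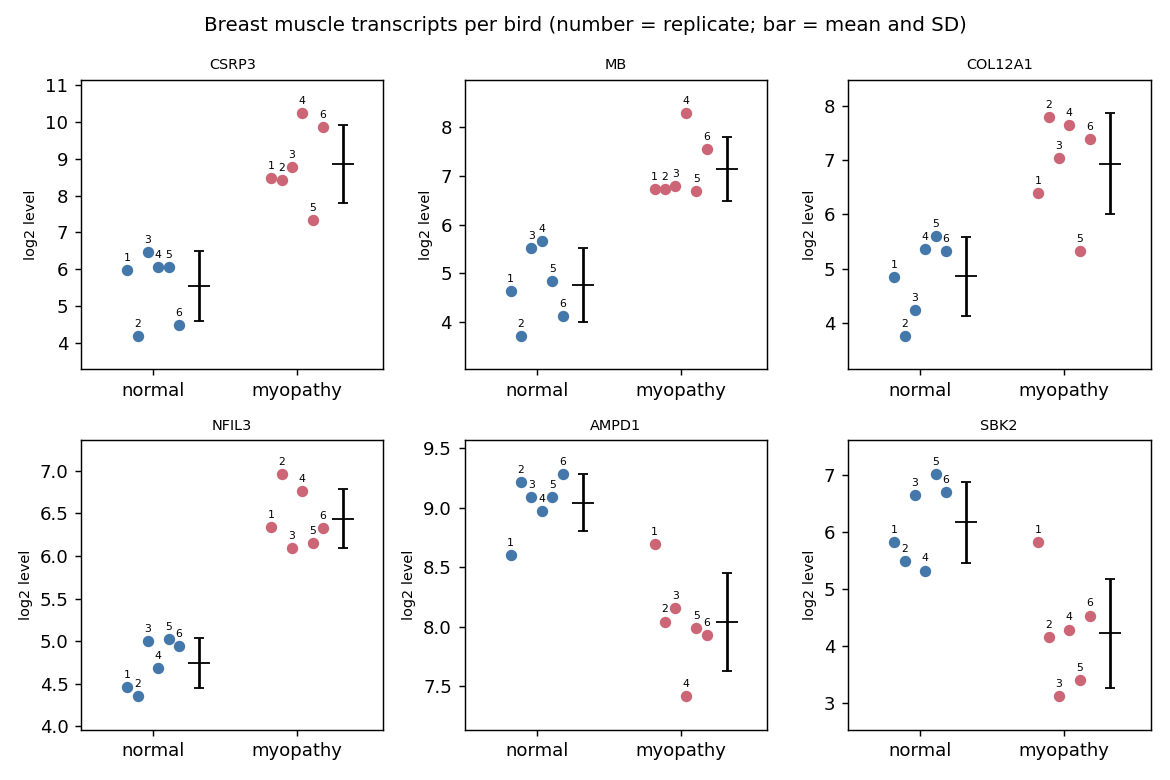
Log2 level of 6 genes (y axis) in each normal and affected bird (points, numbered by replicate), with the group mean and SD as a bar. All 6 affected birds lay above all normal birds for CSRP3, MB and NFIL3, and 5 of 6 lay below all normal birds for AMPD1 and SBK2.

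All 12 birds are labelled male, but 3 arrays of the normal group carried transcripts of the W chromosome, which in birds is present only in females. HINTW, a W-linked gene repeated on that chromosome, stood at 8.51, 9.41 and 9.27 on the log2 scale in normal birds 1, 4 and 5, against 2.46 to 2.99 on the other 9 arrays. ATP5F1AW, the W-linked copy of an ATP synthase gene, was at 7.87 ± 0.22 (SD, n = 3) on these 3 arrays and at 3.67 ± 0.34 on the other 9. Z-linked genes, measured as a median deviation relative to autosomal genes, lay between -0.18 and -0.15 on the 3 arrays and between 0.0098 and 0.096 on the others. In affected minus normal muscle, the median Z-linked cluster was 0.16 higher with all arrays and 0.03 higher without these 3. Of 545 named Z-linked clusters 19 were called higher and none lower, against 81 higher of 11691 on autosomes (Fisher's exact test, p = 7.07e-08, across clusters, which are not independent). In a fit without the 3 arrays, chosen after the HINTW level was seen, 3 clusters passed. With HINTW as a covariate 9 passed. HINTW nearly marks these 3 arrays alone, so the covariate fit compares nearly the same birds as leaving them out. Wherever both are given, the covariate fit is therefore no second, independent check. The 115 autosomal genes called with all arrays kept a median 1.05 of their difference without the 3 arrays, at adjusted p from 0.0532 to 0.192.

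**Figure D2:**
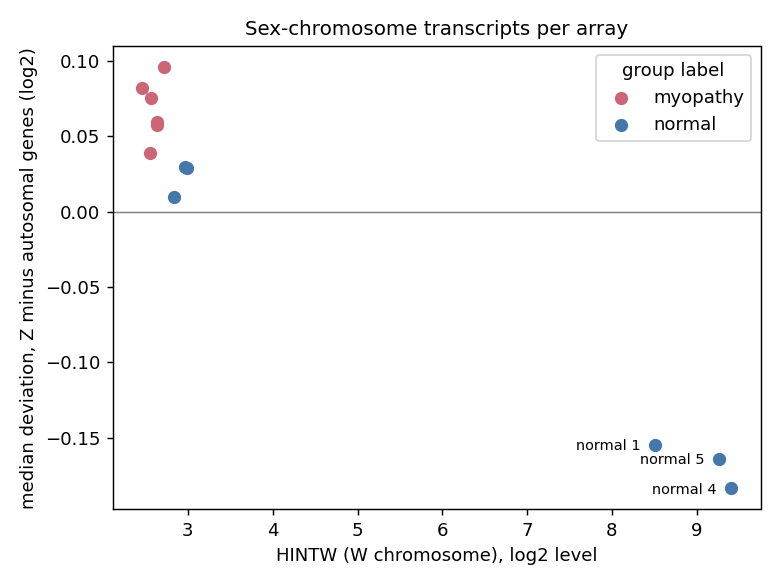
HINTW level (x axis, log2) against the median deviation of Z-linked minus autosomal genes (y axis, log2) for each of the 12 arrays, coloured by group label. Normal birds 1, 4 and 5 lie apart at HINTW levels of 8.51, 9.41 and 9.27.

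The breast muscle is built almost wholly of fast fibres. Of 18 measured slow fibre genes 2 rose: CSRP3, by 3.30 ± 0.50 (log2 difference ± SE, adjusted p = 0.0175), and MB, by 2.37 ± 0.36 (adjusted p = 0.0169). The other 16 did not pass over all clusters, and 8 of the 18 were higher when adjusted over the list alone. As a list, these genes shifted upward in limma's camera test (adjusted p = 0.00545), with a median difference of 0.69, but not with an estimated correlation between genes (adjusted p = 0.337). The median was 0.30 without normal bird 2 and affected bird 4. Muscle stretch and stress genes shifted the same way, with a camera adjusted p of 0.0124, again an adjusted p of 0.337 with an estimated correlation, and an adjusted p of 0.0636 with clusters above the median level only. Of their 23 measured members 3 rose over all clusters and 8 were higher when adjusted over the list alone. Besides CSRP3, which both lists hold, these were CRYAB, a small chaperone that protects the sarcomere, at 0.76 ± 0.14 (adjusted p = 0.0328), and SMPX, a small muscle protein, at 0.97 ± 0.22 (adjusted p = 0.0499).

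Fast fibre genes passed in both directions. MYH1G, a fast skeletal myosin heavy chain of the chicken, rose by 2.30 ± 0.43 (adjusted p = 0.0379), while AMPD1 fell to 0.498 of its normal level (adjusted p = 0.0316). The other 21 of 23 measured members did not pass over all clusters, and 2 were higher and 1 lower when adjusted over the list alone, where MYH1C, named after its value was seen, joined at 1.25. The list as a whole was not called (camera adjusted p = 0.385); its median difference was -0.06 and its mean 0.16, so median and test differed in sign from the mean. By the exact permutation of list means it was called higher (adjusted p = 0.0277), and after quantile normalization its median was 0.01. Of 31 calcium handling genes none passed, with a camera adjusted p of 0.204 (called lower at 0.0332 without the 3 arrays with W transcripts and at 0.0417 with HINTW as a covariate), and ORAI1, a store-operated calcium channel, had a difference of -0.41 ± 0.11 (adjusted p = 0.0757). The calcium list's median of -0.08 and mean of 0.0020 differed in sign.

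Collagens, proteoglycans and matrix processing enzymes shifted upward as lists in camera, at adjusted p of 3.49e-05, 9.02e-07 and 1.83e-05. With an estimated correlation between genes the adjusted p was 0.337 for each. By fry it was 0.0369, 0.0489 and 0.0369, and by the exact permutation of list means 0.0277 for each. Of 17 measured collagen chains, COL12A1 rose by 2.08 ± 0.42 (adjusted p = 0.0392), and 10 were higher when adjusted over the list alone. The median collagen difference was 0.93, 0.62 without normal bird 2, and 0.50 without normal bird 2 and affected bird 4. Of 34 proteoglycans and matrix glycoproteins none passed over all clusters, and 11 were higher when adjusted over the list alone. LAMA2, a laminin chain of the muscle basement membrane, stood at 6.54 in normal and 7.54 in affected muscle (adjusted p = 0.0553). Among 30 matrix processing enzymes none passed over all clusters, and 8 were higher over the list alone. SERPINH1, the chaperone of collagen folding, had a difference of 1.04 ± 0.24 (adjusted p = 0.0543).

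Enzymes making glycosaminoglycan chains were not called as a list (camera adjusted p = 0.392). Within it UGDH, which makes the UDP-glucuronate used to build these chains, rose by 1.15 ± 0.21 (adjusted p = 0.0374). CHST1, a sulphotransferase, changed by -0.37 ± 0.08 (adjusted p = 0.0452), from 3.94 to 3.57. These levels lie close to the 3.67 ± 0.34 (SD) of ATP5F1AW on arrays without W transcripts, so CHST1 may be near background. The same holds for any other gene named in this text in a group where its mean is under 3.67. The remaining 36 of 38 did not pass over all clusters, and 5 were higher and 3 lower adjusted over the list alone. Besides UGDH and CHST1 these were NDST2 (0.43), DSEL (0.58), DSE (0.41), XYLT1 (0.56), HYAL2 (-0.35) and CHST9, named after their values were seen. CHST9 stood at 2.71 and 2.34, under the 2.99 that HINTW reached on arrays without W transcripts, and is not distinguishable from background here. Without the 3 arrays with W transcripts 1 was higher and 1 lower over the list alone. TGF-beta signalling and fibroblast genes shifted upward in camera (adjusted p = 0.0271), but not with an estimated correlation (adjusted p = 0.576), with none of 32 past the test over all clusters and 1 adjusted over the list alone. That gene was PDGFRA, the receptor that marks mesenchymal progenitors, at 1.46 ± 0.37 (adjusted p = 0.063), and without the 3 arrays 7 were higher over the list alone. The call was also lost without normal bird 2 (adjusted p = 0.0876), normal bird 3 (0.087) or affected bird 4 (0.0593), without normal bird 2 and affected bird 4 together (0.178), and with clusters above the lower quartile only (0.0959). Neither fry (adjusted p = 0.123) nor the exact permutation of list means (adjusted p = 0.0909) called it. Cartilage and tendon genes were not called as a list (camera adjusted p = 0.418): none of 18 passed over all clusters and 1 over the list alone, COMP, a tendon and cartilage matrix protein, at 2.01 ± 0.45 (adjusted p = 0.0504). The cartilage list's median of -0.04 and mean of 0.10 differed in sign. Beside these matrix lists, normal bird 2 stood apart, with a mean collagen deviation of -1.12 against -0.35 to 0.0046 in the other normal birds.

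**Figure D3:**
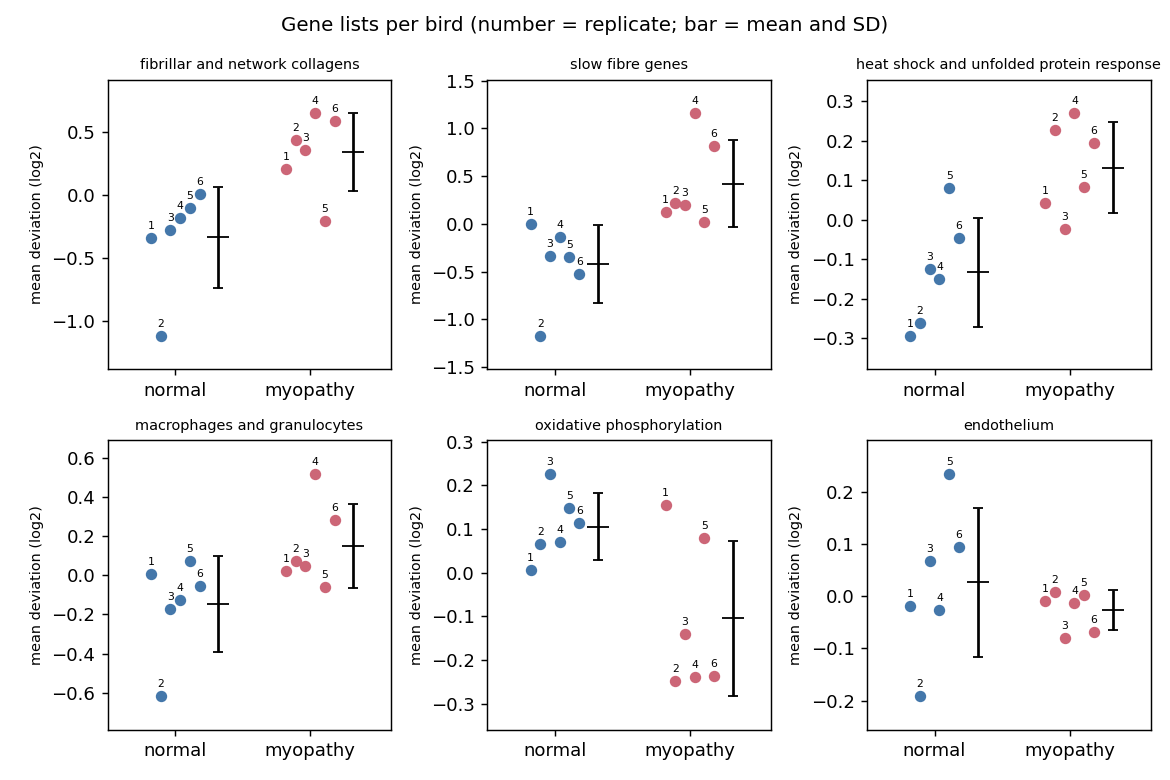
Mean deviation of the members of 6 gene lists from their mean over all arrays (y axis, log2) in each bird (points, numbered by replicate), with the group mean and SD as a bar. Normal bird 2 is lowest for the collagen list at -1.12, the slow fibre list is higher in all 6 affected birds than in any normal bird, and the endothelial list overlaps between groups.

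Nuclear genes of the respiratory chain shifted downward as a list in camera, though not in the other list tests. Of 48 measured members 6 had a positive difference, the median was -0.24, and camera gave an adjusted p of 1.41e-07. The adjusted p was 0.337 with an estimated correlation, 0.0656 by fry and 0.0909 by the exact permutation of list means. The list mean lay below every normal bird in 4 of the 6 affected birds, and within the normal range in affected birds 1 (0.16) and 5 (0.08). No member passed over all clusters, and 3 were lower adjusted over the list alone. These were ATP5E, a small subunit of the ATP synthase, at -0.54 ± 0.12 (adjusted p = 0.0537), and NDUFB4 and NDUFV2 of complex I, at -0.50 ± 0.12 and -0.44 ± 0.11, the last 2 named after their values were seen. Without the 3 arrays with W transcripts none of the 48 passed over the list alone, while camera gave an adjusted p of 4.2e-08. Of 19 citric acid cycle genes none passed over all clusters, and 1 was higher adjusted over the list alone. It was the Z-linked ACO1, with a difference of 0.50 ± 0.13 (adjusted p = 0.0699 over all clusters). That list was not called (camera adjusted p = 0.417) with all arrays, but was called lower without the 3 arrays with W transcripts (adjusted p = 0.0177, median -0.21) and with HINTW as a covariate (adjusted p = 0.0261). Not called either were glycolysis (0.638), glycogen metabolism (0.291, but 0.0103 and lower with clusters above the median level only) and fatty acid oxidation (0.291).

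Within glycolysis none of 25 passed over all clusters, and 1 was higher adjusted over the list alone. It was FBP1, a Z-linked gluconeogenic phosphatase, at 0.56 ± 0.13 (adjusted p = 0.0575 over all clusters). The glycolysis list's median of -0.06 and mean of 0.02 differed in sign. Of 21 glycogen genes PPP1CB, a catalytic subunit of protein phosphatase 1, rose by 0.49 ± 0.09 (adjusted p = 0.0379). Adjusted over the list alone 3 glycogen genes were lower, PRKAB2 (-0.55), PGM2L1 (-0.62) and PRKAG3 (-0.81), all named after their values were seen. Of 31 fatty acid oxidation genes ACAA2, a Z-linked thiolase, rose by 0.87 ± 0.16 (adjusted p = 0.0344), and without the 3 arrays with W transcripts its difference was 0.54. Over that list alone CPT2 (0.35) and FABP3 (0.45), named after their values were seen, were higher too. Adipocyte and lipid storage genes shifted upward in camera (adjusted p = 0.00608), with an adjusted p of 0.337 with an estimated correlation and 0.0636 with clusters above the median level only. None of the 30 passed over all clusters, and 3 were higher and 1 lower adjusted over the list alone. LPL, the Z-linked lipoprotein lipase, had a difference of 0.93 ± 0.23 (adjusted p = 0.0612). The others were CD36 (0.88), APOA1 (1.11) and ME1 (-0.51), named after their values were seen.

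Of 33 measured heat shock and unfolded protein response genes 2 rose: HSPH1, a large cytosolic chaperone, by 1.25 ± 0.19 (adjusted p = 0.0169), and HSPD1, the mitochondrial chaperonin, by 0.58 ± 0.10 (adjusted p = 0.0328). Adjusted over the list alone, 14 were higher and 1 was lower. Camera called the list higher at an adjusted p of 3.49e-05, and the adjusted p was 0.337 with an estimated correlation. Proteolysis and autophagy genes also shifted upward (camera adjusted p = 0.00447), with an adjusted p of 0.283 with an estimated correlation. Of 39 members 1 rose, CAST, the Z-linked calpain inhibitor, by 0.73 ± 0.16 (adjusted p = 0.046), and 4 were higher adjusted over the list alone, the others being FBXO30 (0.41), CTSZ (0.55) and CTSC (0.67), named after their values were seen. Antioxidant and detoxification genes were not called (camera adjusted p = 0.105), though they were by fry (0.0369) and by the exact permutation of list means (0.0277). Of 39 members HMOX1, which degrades haem, rose by 0.69 ± 0.15 (adjusted p = 0.0499), and 4 were higher and 3 lower adjusted over the list alone. Besides HMOX1 these were GSTT1L (1.01), TXNRD1 (0.46), GPX8 (0.68), GSTZ1 (-1.06), NFE2L2 (-0.54) and GSTA4, named after their values were seen. GSTA4 stood at 2.24 and 1.93, under the 2.99 that HINTW reached on arrays without W transcripts, and is not distinguishable from background either. Hypoxia response genes were not called (0.291; exact permutation of list means 0.0315), with none of 24 past the test and LOX, a Z-linked collagen crosslinking enzyme, at 0.81 ± 0.25 (adjusted p = 0.0995).

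Myogenesis and regeneration genes were not called as a list with all arrays (camera adjusted p = 0.128). The list was called higher without the 3 arrays with W transcripts (adjusted p = 0.0235), with HINTW as a covariate (0.0168) and without normal bird 1 (0.0355). MUSK, the Z-linked receptor kinase of the neuromuscular junction, rose by 0.60 ± 0.11 (adjusted p = 0.0317), and CHRND, an acetylcholine receptor subunit, by 0.76 ± 0.17 (adjusted p = 0.0471). The other 31 of 33 measured members did not pass. Of 45 cell cycle genes none passed. The list was not called with all arrays (camera adjusted p = 0.132) and was called higher after quantile normalization (0.00875), without normal bird 1 (0.0323), without the 3 arrays (0.0332) and with the covariate (0.0445), and NUSAP1, a spindle protein, was at 0.36 ± 0.13 (adjusted p = 0.126). Among 47 ribosomal proteins RPL3 rose by 0.87 ± 0.18 (adjusted p = 0.0425) in the brighter of its 2 clusters, the other being at 0.42 (adjusted p = 0.186). Over the list alone RPS6 (0.47), RPS3 (0.45), RPL23A (0.34) and RPS20 (-0.37) passed too, named after their values were seen. The ribosomal list was not called (camera adjusted p = 0.701), and its median of -0.04 and mean of 0.0077 differed in sign. It was called higher without the 3 arrays with W transcripts (median 0.06, adjusted p = 0.0369) and with HINTW as a covariate (adjusted p = 0.0417).

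Markers of other cell types moved unequally. Macrophage and granulocyte genes shifted upward in camera (adjusted p = 0.0124), but not with an estimated correlation (adjusted p = 0.656), with none of 36 past the test over all clusters and 3 higher adjusted over the list alone. MRC2, a collagen-binding receptor also found on fibroblasts, had a difference of 0.88 ± 0.21 (adjusted p = 0.0583). The others were TREM2 (0.57) and CD44 (0.90), named after their values were seen, and without the 3 arrays with W transcripts 10 were higher over the list alone. The call was also lost without normal bird 2 (adjusted p = 0.0836) and without affected bird 4 (adjusted p = 0.0593), and without both at 0.243. Neither fry (adjusted p = 0.186) nor the exact permutation of list means (adjusted p = 0.0808) called it. T and natural killer cell genes (camera adjusted p = 0.38; lower at 0.0169 without normal bird 2 and affected bird 4) and B and plasma cell genes (0.653) were not called. CCR9, a chemokine receptor, was at -0.23 ± 0.08 (adjusted p = 0.118), and EBF1, a transcription factor of B cells and adipocytes, at 0.60 ± 0.20 (adjusted p = 0.114). The B cell median of -0.07 and mean of 0.08 differed in sign. Inflammatory mediators were not called (0.38) but were higher with clusters above the median level only (0.0481), and of 57 members IL1B, a cytokine at low signal here, changed by -0.44 ± 0.08 (adjusted p = 0.0383). Over that list alone AVD (1.28), IL1R1 (0.82) and IL18 (0.61), named after their values were seen, were higher.

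Vessel, nerve, blood and epithelial markers were not called as lists with all arrays. Endothelial genes had a median of -0.06 (camera adjusted p = 0.174), between -0.09 without normal bird 4 and -0.01 without normal bird 6. They were called lower without normal bird 2 (0.0367), without normal bird 2 and affected bird 4 (0.0169) and with clusters above the median level only (0.0392), and of 29 members SOX7, an endothelial transcription factor, changed by -0.54 ± 0.10 (adjusted p = 0.0389), with its second cluster at -0.30 (adjusted p = 0.106). Smooth muscle and pericyte genes had a median of 0.0054 while camera pointed downward (adjusted p = 0.69), with PDGFRB at 0.50 ± 0.18 (adjusted p = 0.141). Of 12 Schwann cell and nerve genes, 1 rose, CRYAB, which muscle fibres also express (camera adjusted p = 0.905); the median of -0.01 and mean of 0.03 differed in sign. Of 14 red blood cell genes (camera adjusted p = 0.291) CA2, a carbonic anhydrase, changed by -0.66 ± 0.14 (adjusted p = 0.0468). Skin and epithelial genes were not called (0.0624) but were lower without normal bird 2 (0.0367), 5 (0.0372) or 6 (0.048) and without normal bird 2 and affected bird 4 (0.0342), with KRT5 at -0.34 ± 0.13 (adjusted p = 0.152).

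Outside the lists, the smallest p of any named gene belonged to NFIL3, a Z-linked basic leucine zipper repressor, which rose 3.24-fold, from 4.74 ± 0.29 (SD, n = 6) to 6.44 ± 0.35 (adjusted p = 0.00276). Its call was kept when any 1 array was left out, at adjusted p from 0.00444 to 0.0156, and stood at 0.05002 without the 3 arrays with W transcripts, where its difference was 1.68. SPG20, which encodes spartin, rose by 0.85 ± 0.11 and GPD1L, a glycerol-3-phosphate dehydrogenase relative, by 0.62 ± 0.08, both at an adjusted p of 0.0143. Other large rises were in CLMN (2.08 ± 0.44), MAP1B, a Z-linked microtubule-binding protein (1.74 ± 0.37), ACKR4, a scavenging chemokine receptor (1.43 ± 0.30), and SNAI2, a mesenchymal transcription factor (1.34 ± 0.25). SYNJ2, LRRC30, ARRDC3 (Z-linked) and IMPG2 rose by 1.18, 1.16, 1.12 and 1.09. Adjusted p for these 8 genes lay at or below 0.0486. The second cluster of CLMN was at 1.42 (adjusted p = 0.083) and that of SNAI2 at 0.55 (adjusted p = 0.306). In normal muscle CLMN, SYNJ2 and IMPG2 stood at 3.47, 3.47 and 3.32, which may be near background, so the size of their rise is uncertain.

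The largest fall was in SBK2, a muscle kinase, which changed by -1.95 ± 0.42 (adjusted p = 0.0471) and stood at 0.259 of its normal level. PON1, a paraoxonase (-0.86 ± 0.18), FAM46B (-0.82 ± 0.17), CNGB1, a cyclic nucleotide-gated channel subunit (-0.77 ± 0.13), and ETNPPL, which degrades phosphoethanolamine (-0.70 ± 0.11), fell at adjusted p between 0.024 and 0.046. The second cluster of CNGB1 was at -0.28 (adjusted p = 0.0847). P2RY1, a receptor for extracellular ADP, changed by -0.70 ± 0.12, TOB1, an antiproliferative regulator, by -0.66 ± 0.13, TTC32 by -0.70 ± 0.15 and the microRNA gene MIR1557 by -0.71 ± 0.15. TTC32 stood at 3.35 in affected muscle, which may be near background. HOXA3 changed by -0.86 ± 0.19 (adjusted p = 0.046) in its brighter cluster, while its dimmer cluster had a difference of 0.52 (adjusted p = 0.111), so the 2 clusters of that gene point opposite ways.

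Other counts adjusted over the list alone also moved without the 3 arrays with W transcripts. They were 17 for proteoglycans, 9 for matrix processing enzymes, 7 for regeneration, 6 for proteolysis, 5 higher for adipocytes and 1 for fatty acid oxidation. Antioxidant genes had 7 higher and 2 lower, muscle stretch genes 7 higher and 2 lower, and heat shock genes 13 higher and 0 lower. Citric acid cycle genes and Schwann cell genes each had 1 higher and 1 lower. None passed among glycolysis genes, inflammatory mediators, endothelial genes and red blood cell genes, and no glycogen gene was lower. Of the ribosomal proteins 1 was higher and none lower.

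Over all lists, camera called 11 of 32, 10 higher and 1 lower. With an estimated correlation between genes it called 0 of 32. By fry, which asks whether a list's genes move on balance one way, 9 lists passed, 8 of them among the 11, and 28 lists passed for change in either direction. The 8 shared lists were collagens, proteoglycans, matrix processing enzymes, muscle stretch, slow fibre, adipocyte, heat shock and proteolysis genes. Each also passed the exact permutation of list means, added after the data were seen (adjusted p = 0.0277).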

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

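All tests in this part were chosen after the result was seen, except the random splits of the arrays, which were planned before. A bird far from the other 5 of its group was marked in 17 of the 188 groups of 6 examined, where chance alone marks 9.4.

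The W-chromosome signal was found on 3 normal arrays and on no affected array: HINTW stood at 8.51 in normal bird 1, 9.41 in normal bird 4 and 9.27 in normal bird 5, against at most 2.99 elsewhere. A fault of a single probe set is argued against by 8 of the 13 named W genes other than HINTW, each higher on all 3 arrays than on the other 9, where chance gives 0.0591 genes. A trace of hen RNA is argued against by the Z-linked median, whose highest value on the 3 arrays lay -0.16 from the lowest of the others, with an SD of 0.03 among those 9. The value itself, -0.15 against 0.0098, is consistent with hens among the birds labelled male, as a hypothesis. A mixture holding mostly hen tissue stays open, as does an exchange of samples, which would change what the normal label of these arrays means, and no record of the birds was tested.

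The Z-linked excess in affected muscle was 0.172 relative to autosomal genes and 0.0444 without the 3 arrays, lower than the 0.111 left by any other choice of 3 normal arrays, which may reflect an uneven sex composition of the groups. The myopathy alone is argued against: no affected bird exceeded any of the other 3 normal birds by more than 0.0861. A smaller part stays open, since these 9 birds still differed by 0.05 (exact permutation p = 0.0238). Without the 3 arrays the 19 called Z-linked genes kept a median 0.973 of their difference. The 115 called autosomal ones kept a median 1.05, with a lower quartile of 0.948. Leaving out any other 3 normal arrays gave medians from 0.898 to 1.10 for them. These shares cannot decide about uneven sex composition as a cause. A gene shifted only on the 3 arrays would vary too much among the normal birds to be called. The adjusted p of the autosomal ones no longer passed with 9 arrays, where their median SE was 0.13 against 0.11 with 12.

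The collagen and slow fibre lists shifted upward in camera, though at an adjusted p of 0.337 each with an estimated correlation. In normal bird 2 the collagen, matrix enzyme and macrophage means were -1.12, -0.69 and -0.62, and that bird was low in PDGFRA (3.93, others at least 5.79), COMP (5.24, others at least 6.93) and ARRDC3 (4.63, others at least 5.35), yet 0.769 of the collagen shift remained without it. A larger share of every cell type other than muscle fibres is argued against by the vessel lining genes. Collagens, not cut by level themselves, rose by 0.74 more than vessel lining genes above a log2 level of 5 (exact permutation p = 0.00649). Against all 29 vessel lining genes it was 0.73 more (p = 0.00649, exact). Collagens rose by 0.65 more than smooth muscle genes above that level (p = 0.013, exact). That list as fixed shares TPM1, TPM2 and PLN with the fibre lists, so it is no clean marker of other cells. The other lists gave mixed results. Collagens rose by 0.38 more than all 36 macrophage genes (p = 0.0108, exact), but by 0.0060 more than the 12 above that level (p = 0.95, exact). For nerve genes it was 0.64 more than all 12 (p = 0.00866, exact), but 0.20 more than the 2 above that level, CRYAB and PMP22 (p = 0.314, exact). Without the 3 arrays the collagen and slow fibre shifts were 1.18 and 1.30 times as large. They were not lost, which argues against uneven sex composition as their whole cause. The growth itself is no evidence, since the low normal bird 2 (-1.12 for collagens, -1.17 for slow fibre genes) then weighs more. Normal birds 3 and 6 stood at -0.28 and 0.0046 for collagens, against an affected mean of 0.34, with affected bird 5 (-0.21) between them. For slow fibre genes they stood at -0.33 and -0.52, against an affected mean of 0.42. No list test was run without normal bird 2 and the 3 arrays together. A change in fibroblasts or macrophages, or in where the fillet was sampled, stays open and was not tested.

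Other birds far from their group are given as values. Normal bird 2 was high in HOXA3 (7.37). Normal bird 1 was high in SYNJ2 (4.01), CA2 (8.69) and CCR9 (3.64), and normal bird 4 was low in IMPG2 (2.80). Affected bird 1 was low in GPD1L (5.67) and affected bird 2 high in KRT5 (3.75). Affected bird 4 was high in LPL (7.61), in EBF1 (7.16), and in the means of the B cell list (0.36) and the inflammatory mediator list (0.38).

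Among 100 of the 462 splits of the arrays into 6 and 6, drawn at random with the real one included, 1 gave as many calls, the real one with 238, and the highest other gave 2. For calls at 2-fold it was again 1 of 100, the real one with 42 and the highest other with 2, so chance is argued against for both counts. For lists called by camera, 21 of 100 splits gave as many, with 11 in the real split and 16 in the highest other, so chance cannot be excluded for the number of lists. No other split that put the 3 arrays with W transcripts on 1 side made a call, in the 18 drawn. This cannot decide about sex composition, since a gene shifted only on those arrays would vary too much within its side to be called.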

How the results depend on the processing

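The alternatives with the W arrays, the covariate, autosomal genes, both end arrays and the exact test of list means were chosen after seeing the data. The total of 238 calls (131 higher, 107 lower, 42 at 2-fold) ranged from 1 to 588 when 1 array was left out (1 to 287 higher, 0 to 301 lower, 1 to 81 at 2-fold). It became 455 (279, 176 and 69) with clusters above the median level only and 384 (226 higher, 65 at 2-fold) above the lower quartile, where fewer clusters were tested. Without moderation it was 35 (20, 15 and 2), and with unequal variances 0 in every count, with 4095 at an unadjusted p under 0.05. Median centring gave 225 higher and array weights 199 higher. Named clusters only gave 68 lower, and named clusters on autosomes only 55 lower. Without the 3 normal arrays with W transcripts there were 3 calls (3 higher, 0 lower, 2 at 2-fold), with HINTW as a covariate 9 (8, 1 and 4), and without normal bird 2 and affected bird 4 a single call (1 higher, 0 lower, 1 at 2-fold). The cause was not tested. All main calls that were tested kept their sign in each of these fits. This was fixed in advance for the variance models and filters, which leave the group means as they are. It was also likely for fits that share most arrays. The count of 11 lists was 0 with an estimated correlation and 9 to 16 under the other alternatives. The ribosomal list turned upward without the 3 arrays (median 0.0611, adjusted p = 0.0369) and with the covariate (0.0572, adjusted p = 0.0417). By the exact permutation of list means, 11 lists passed, 8 of them shared with camera, and the fast fibre list was positive (0.16, adjusted p = 0.0277). The difference on component 1 passed the exact test in every setting tried. It was 24.5 (exact permutation p = 0.00649) with named autosomal clusters only, which are fewer. The median log2 ratio of SDs between birds was -0.10 (p = 0.442 by permutation of values centred on their group mean, which is approximate). It ran from -0.195 to 0.0241 when 1 array was left out and was 0.21 without the 3 arrays, never past the test.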

Other observations

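All values in this part were looked at after the data were seen. SPP1, which encodes osteopontin, a secreted matrix phosphoprotein made by macrophages and other cells, was not called with all arrays, at 1.34 ± 0.61 (adjusted p = 0.215), with an SD of 1.61 among the normal birds. It was 1 of the 3 clusters called without the 3 arrays with W transcripts, at 2.71 (adjusted p = 0.0324), where the other 2 had no gene listed. With HINTW as a covariate, a fit that nearly repeats leaving out the 3 arrays, SPP1 was also called, at 2.81 (adjusted p = 0.039). The other named calls of the covariate fit were SPG20, NFIL3, ANXA2, PGM3 and PLCB2. ANXA2, a calcium-dependent membrane-binding protein, was at 0.88 ± 0.27 with all arrays (adjusted p = 0.0997) and at 1.51 in that fit (adjusted p = 0.039).

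NFIL3 was the single call left without affected bird 6, at 1.72 (adjusted p = 0.0118), and without normal bird 2 and affected bird 4 together, at 1.55 (adjusted p = 0.0248).

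BF2, a class I gene of the chicken major histocompatibility complex, fell into a high and a low range that did not follow the groups. It was at 5.20 in normal bird 5, 5.96 in affected bird 1 and 5.02 in affected bird 4, and between 8.68 and 9.66 in the other 9 birds.

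The median SD per cluster was 0.18 in affected and 0.20 in normal birds on the log2 scale. The SDs were compared through their ratio within each cluster, by permuting values centred on their group mean, which makes the p approximate. The median log2 ratio of SDs, -0.10 (permutation p = 0.442), turned positive without normal bird 1 (0.02) and without the 3 arrays with W transcripts (0.21, permutation p = 0.417). Affected birds 4 and 6 had the highest scores on component 1, 41.4 and 28.2, and affected bird 1 the lowest of its group, 6.93.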
